A study of Parhyale hawaiensis with 5 samples.

How the data were processed

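Nuclei were isolated from pooled legs and sequenced as droplet libraries, per the labels' protocols, and the 5 libraries were uninjured legs of 3 pools of animals and regenerated legs of 2 of them. Groups were taken from the treatment label and pools from the batch label. The pairing of a regenerated library with the uninjured library of its pool comes from the protocol, which took the uninjured legs from the opposite side of the animals that regenerated. It was therefore in the design before the data were examined. Replicate numbers were given in accession order and pair nothing. A pool of legs is the replicate, and nuclei were never treated as replicates.

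The deposited matrices hold UMI counts per gene and barcode, whole numbers that were not normalised. The submitters' processing notes name Cell Ranger 6.0.1 and Seurat 4, while the file headers name Cell Ranger 4, and which of them made the deposited counts is not given in the sources used here. The genome build is not given there either, and scaffold positions are those of the deposited annotation, counted from 1. The 24858 genes of the matrices are those of the deposited intron annotation, and the 42657 genes found only in the deposited exon annotation, 42655 of them models with 1 exon, were not counted. UMIs followed intron length (Spearman 0.765 across nuclear genes with a UMI) more than exon length (0.374), so nuclear genes with short introns tended to have few counts. The median was 0 UMIs for genes under 2000 intron bp and 503 UMIs for those with 10000 or more. The authors also deposited a list of nuclei per library, whose barcodes all had at least 101 UMIs and were used without a further minimum.

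Free RNA was estimated from the barcodes off those lists with 10 to 100 UMIs. It amounted to 9.10% of the UMIs of kept nuclei in the 0-month library, 11.6% and 11.5% at 2 months, and 7.20% and 7.67% at 6 months, uninjured before regenerated. It was not removed from the counts. The share of a gene's UMIs that it would give was computed from the profile of those barcodes, their mean UMIs and the number of nuclei, and can exceed 100%. Doublets were marked with Scrublet at an expected rate of 0.8% per 1000 nuclei. The automatic threshold marked 0 nuclei in 4 libraries, where the nuclei with the highest scores were taken up to the expected rate, and 14.0% in the regenerated library at 2 months. In all, 7941 nuclei were left out and 60479 kept.

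Kept nuclei were scaled to 10000 counts, log-transformed and reduced to 2000 variable genes, each scaled within its library and clipped at 10 SD. The steps were 30 principal components, 20 neighbours and Leiden clustering at a resolution of 0.5 (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, seed 0). A cluster was described by up to 3 genes found in at least 20 percentage points more of its nuclei than of the others, ranked by fold with 10 CPM added. No gene names or genome sequence were used here for nuclear genes, so the planned gene lists and cell type markers could not be applied, clusters carry numbers, and at most 2 identifiers per direction are printed for a comparison.

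Counts were summed per library, and per library and cluster where each of the 4 paired libraries had at least 50 nuclei. They were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test, R 4.3.3) with pool and treatment as terms in the 4 libraries of the 2 complete pools, which leaves 1 residual degree of freedom. In 7 of the 9 clusters with a call edgeR estimated no gene-specific spread. The SE beside a log2 fold is the absolute log2 fold divided by the square root of the F statistic. It follows the fitted spread, which is mostly shared across genes, and does not measure how far the 2 pools differed for that gene. P-values were adjusted by Benjamini-Hochberg at 0.05 over all genes, or within a cluster. Numbers of nuclei per cluster were tested in the same design with the number of kept nuclei as library size. Intervals on a single share are exact binomial ones at 95%, a count of 0 was given the limit of 3 counts, and both cover counting error only. CPM beside a test are scaled by TMM.

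The genes named were fixed by rule before the data were examined: up to 10 per direction with the largest change among genes past the threshold, in the same direction in both pools and with a mean of at least 10 CPM. Where fewer than 3 passed over all nuclei, the 3 with the smallest p per direction applied, of which 2 are printed. In clusters the rule took 2 per direction. MSTRG.28103 and MSTRG.2350 stand by that rule; MSTRG.38102 as a gene of many clusters and the single call of cluster 14 were chosen after their values were seen. Similarity was Pearson's r of log2 CPM with a prior count of 2 over genes with at least 10 UMIs in at least 2 libraries, and the total variation distance of cluster shares.

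The fit was tested on simulated counts drawn from the pool means and library sizes of the real genes, with 200 genes changed 1.5-fold, 2-fold or 4-fold in 5 runs. Dispersions varied between genes with 6 degrees of freedom in every comparison. False calls made up 31.4% of the calls in the simulation of all nuclei. No simulated call had the wrong direction, and 4.81% to 5.29% of unchanged genes had p under 0.05. The alternatives listed before the data were examined were fits without the pool block, each library left out in turn, DESeq2 1.42.0, DESeq2 size factors, no filter, thinned counts, genes with over 10% free RNA left out, doublets kept, the expected doublet rate in every library, at least 500 UMIs per nucleus, Leiden resolutions 0.25 and 1, no correction between libraries, and Seurat 5.3.0 RPCA integration. For the descriptive values they were a prior count of 0.5, genes with at least 50 UMIs in every library for the similarity, and at least 200 UMIs for the ratios per pool. Leaving out mitochondrial genes or cluster 15, clustering without mitochondrial genes thinning for the similarity and subtracting the expected free RNA from MSTRG.38102 were added after seeing the data.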

Results

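Single-nucleus RNA sequencing was used to ask whether a leg that has regrown after amputation regains the cells and transcripts of a leg that was never injured. The animal was the amphipod crustacean Parhyale hawaiensis, and every library pooled thoracic legs of large adult males. The 5 libraries came from 3 pools of animals. In a pool sampled 2 months after amputation and in a pool sampled 6 months after it, 1 library held the regenerated legs and 1 held the uninjured legs of the opposite side of the same animals. A further uninjured library, labelled 0 months, came from a pool without regenerated legs. There were thus 3 uninjured and 2 regenerated libraries. Months since amputation and pool of animals were the same split and could not be separated.

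The deposited lists of nuclei held 13083 barcodes for the 0-month uninjured legs, 16914 and 16627 for the uninjured and regenerated legs at 2 months, and 12753 and 9043 for those at 6 months. Their counts of unique molecular identifiers (UMIs, single captured molecules) summed to 4794167, 6132011, 6939709, 5844921 and 3473812. The median nucleus of a library held 235 to 299 UMIs, so a value for 1 nucleus was imprecise, and the comparisons used sums over many nuclei. After every kept nucleus was thinned to 100 UMIs, which left none out, the median number of genes was 90 in the 0-month library, 88 in both libraries at 2 months, and 91 and 92 in the uninjured and regenerated libraries at 6 months. Without thinning it was 203, 183, 219, 233 and 217. The matrices counted introns, and the files gave names to mitochondrial genes only, so nuclear genes appear by identifier and clusters by number.

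Regenerated legs held nuclei of the same 20 clusters as the uninjured legs of their own animals, though cluster 15 held 1 nucleus in the 2-month uninjured library. Genes were scaled within each library before clustering, which removes shifts of a whole library, so shared clusters were partly built in. With no such correction, a cluster lay almost only in the 6-month uninjured library. Cluster 1, the largest, made up 25.7% of the 60479 kept nuclei, and no gene met the rule for describing it. Cluster 18 took 2.43% of nuclei in regenerated legs against 1.52% in uninjured legs at 2 months, and 1.68% against 0.969% at 6 months. Its fitted share was 1.66 times as high in regenerated legs (95% interval 1.04 to 2.65, n = 2 pools, edgeR adjusted p = 0.598). Cluster 12 took 1.55% against 3.04% at 2 months and 2.35% against 2.87% at 6 months, a fitted ratio of 0.644 (95% interval 0.406 to 1.02, edgeR adjusted p = 0.598). Cluster 12 nuclei were among the deepest, with a median of 808 UMIs.

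No cluster passed the test for a change in share. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 20 clusters, with 1, cluster 18, at an unadjusted p under 0.05, and no other tool was run on shares. With the fits assuming a common spread, the 95% intervals were wide: the ratio for cluster 1 ran from 0.677 to 1.62. By counting error alone, 13 clusters differed between the libraries of the 2-month pool and 4 between those of the 6-month pool. Cluster 18 was the only cluster higher in regenerated legs in both by that measure, which covers the counting of nuclei and not the spread between animals. Cluster 9 took 3.07% of nuclei in the regenerated library and 5.28% in the uninjured library at 2 months, but 5.23% and 5.17% at 6 months.

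**Figure D1:**
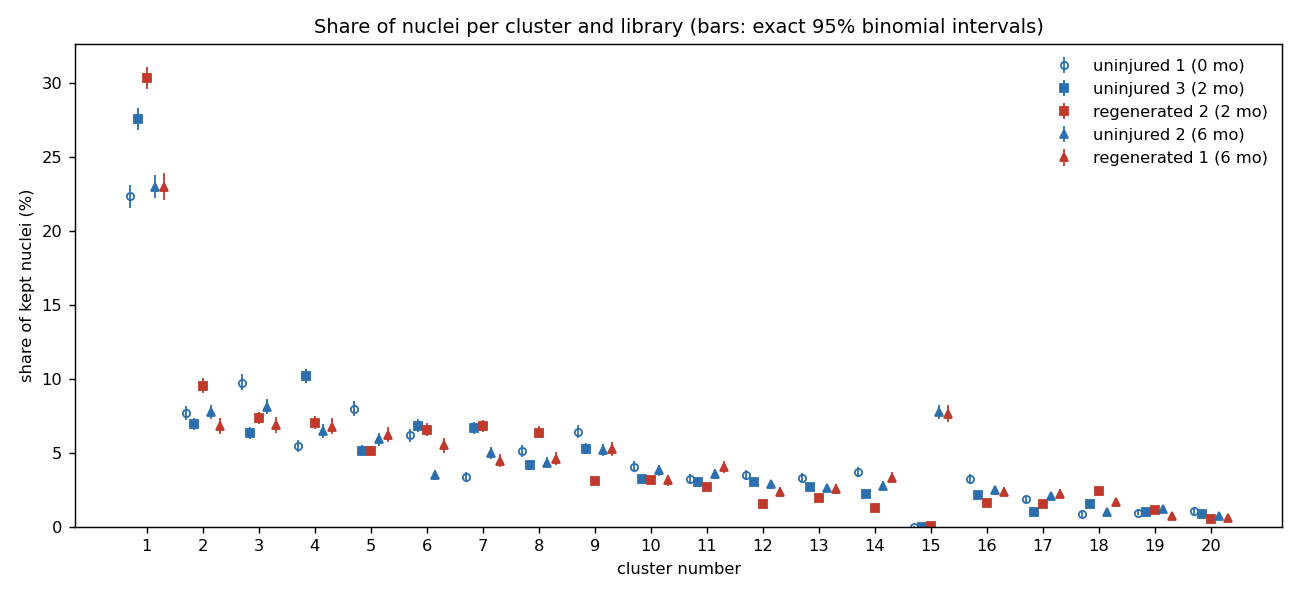
Share of kept nuclei (%, y axis) in each cluster (x axis) for each library, with uninjured legs in blue and regenerated legs in red. Bars are exact 95% binomial intervals and cover counting error only; cluster 15 reached 7.75% and 7.62% at 6 months and 0.0699% or less in the other libraries.

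Cluster 15 separated the pools, not the treatments. It held 887 nuclei (7.75%, exact 95% interval 7.26 to 8.25) in the uninjured and 639 (7.62%, 7.06 to 8.21) in the regenerated library at 6 months. At 2 months it held 1 nucleus in the uninjured and 10 in the regenerated library. The 0-month library had 0 of 11714 nuclei, which allows a share of up to 0.0256%. Its 125 describing genes took 22.4% and 22.2% of the UMIs of its own nuclei in the 6-month uninjured and regenerated libraries, and 3.90% and 3.61% of those of the other nuclei there.

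Each regenerated library resembled the uninjured library of its own pool more than any library of another pool. Pools were taken from the batch label, so shared animals and a shared batch could not be told apart. Across genes, log2 CPM (UMI counts scaled to library size) of the regenerated and uninjured libraries correlated at Pearson r = 0.970 at 6 months and 0.977 at 2 months. The 3 pairs of uninjured libraries from different pools reached 0.929 to 0.959. The distance between cluster shares, the percentage of nuclei that would have to change cluster, was 4.85% at 6 months and 10.2% at 2 months within a pool. Between uninjured libraries of different pools it was 12.0% to 14.7%, and between regenerated and uninjured libraries of different pools 12.6% to 18.4%. Genes are not independent replicates, and these values carry no test. Without cluster 15, which was left out after its distribution was seen, the distance between the 0-month and 6-month uninjured libraries was 8.52%, below the 10.2% within the 2-month pool.

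**Figure D2:**
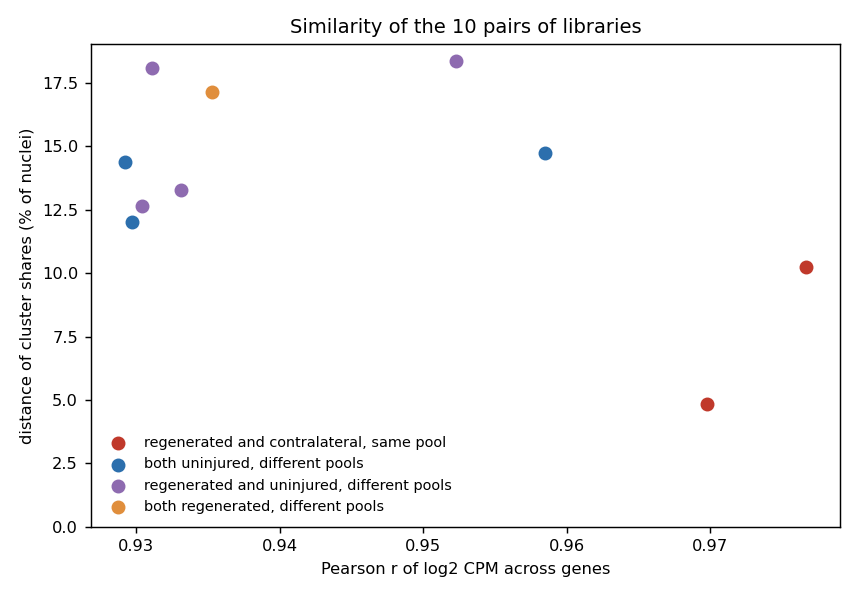
Pearson r of log2 CPM across genes (x axis) against the distance of cluster shares (y axis, % of nuclei) for the 10 pairs of libraries. The 2 pairs of regenerated and contralateral legs, in red, have the highest r, 0.970 and 0.977, and the lowest distances, 4.85% and 10.2%.

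Summed over all nuclei, no gene passed the test between regenerated and uninjured legs. The lowest adjusted p was shared by MSTRG.2350 and MSTRG.28103, which fitted higher and lower in regenerated legs. MSTRG.2350 (scaffold phaw_50.000203c, 139435 to 213623) had 21.2 CPM in regenerated against 3.24 CPM in uninjured legs at 2 months and 46.4 against 6.79 CPM at 6 months. Its log2 fold was 2.74 ± 0.24 (SE, n = 2 pools, edgeR adjusted p = 0.0683). MSTRG.2351 (195977 to 424853 on the same scaffold and strand, overlapping it) had 72.8 against 27.1 CPM at 2 months and 82.7 against 31.4 CPM at 6 months. Its log2 fold was 1.41 ± 0.17 (edgeR adjusted p = 0.220), and reads in the shared stretch may belong to either model. MSTRG.30788 had 66.6 against 138 CPM at 2 months and 16.1 against 35.1 CPM at 6 months, a log2 fold of -1.08 ± 0.17 (edgeR adjusted p = 0.588). MSTRG.28103 had the lowest fitted log2 fold of the genes named here, -4.93 ± 0.46 (edgeR adjusted p = 0.0683). But it rested on the 6-month pool, where 639 UMIs in the uninjured and 12 in the regenerated library were counted against 1 and 1 at 2 months. Without the nuclei of cluster 15, which lay almost only in that pool, it fell under the count filter and could not be tested.

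edgeR's quasi-likelihood test called 0 of 15593 genes, with 808 (5.18%) at an unadjusted p under 0.05, near the share that no change would give. DESeq2 called 2, both higher in regenerated legs and with MSTRG.2350 among them. The fit had 1 residual degree of freedom. On simulated counts of this design it recovered 18% of genes changed 2-fold and 79.6% of those changed 4-fold over all nuclei, so many smaller changes would not be detectable. MSTRG.2350 was among the genes for which free RNA would give over 10% of the counts in a library. Without the pool as a block, edgeR called 0 genes in the same 4 libraries, with 209 at an unadjusted p under 0.05.

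Within clusters, 94 gene and cluster pairs passed the test, 34 higher and 60 lower in regenerated legs, in 9 of the 18 clusters tested. Of the 67476 tests, 3374 (5%) had an unadjusted p under 0.05 with edgeR, the share that no change would give. No general surplus of small p-values thus lay behind the calls. The excess of lower calls did not hold under every setting: without genes of over 10% free RNA 19 were higher and 15 lower, and without the block and regenerated replicate 1 the split was 40 and 32. Cluster 1 held 46 of the 94, 12 higher and 34 lower, against 3 and 2 without genes of over 10% free RNA. Its largest named change was mikado.phaw_50.000203cG42, at 151 against 8.12 CPM at 2 months and 19.5 against 1.59 CPM at 6 months (log2 fold 4.08 ± 0.48, SE, edgeR adjusted p = 3.04e-13). That gene had 161 against 6 UMIs at 2 months and 9 against 1 at 6 months. Free RNA would give 16.0% and 11.0% of its UMIs in the uninjured libraries at 6 and 2 months, and without the block its log2 fold was 2.38 without regenerated replicate 2 and 6.47 without uninjured replicate 3. MSTRG.2350, which did not pass over all nuclei with edgeR, passed in cluster 1 (log2 fold 3.55 ± 0.63, edgeR adjusted p = 1.74e-05), on 1 and 3 UMIs in the uninjured and 20 and 26 UMIs in the regenerated libraries. Without the block its log2 fold was 2.78 without regenerated replicate 1, 4.32 without uninjured replicate 2 and 4.31 without regenerated replicate 2. Free RNA would give 49.2% to 119% of the UMIs behind that call, so its level in cluster 1 nuclei was not established. MSTRG.25719 fell in cluster 1, from 176 to 4.32 CPM at 6 months and from 35.2 to 10.3 CPM at 2 months (log2 fold -3.15 ± 0.40, edgeR adjusted p = 2.55e-11). With counts thinned to equal totals it did not pass (log2 fold -3.61, edgeR adjusted p = 0.305), and without the block its log2 fold was -4.68 without regenerated replicate 2 and -4.22 without uninjured replicate 3. Many of the lower calls of cluster 1, this one included, rested on the 6-month uninjured library: in 25 of the 34 its CPM was over 2 times that of each of the other 3 libraries, and the median log2 ratio of the 34 was -2.45 at 6 months and -0.34 at 2 months. When nuclei were clustered with no correction between libraries, a cluster held 11.1% of the nuclei of that library and at most 0.376% of those of any other. Whether its nuclei carried the lower calls of cluster 1 was not tested.

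Cluster 4, whose nuclei were the deepest with a median of 941 UMIs, held 23 calls, 10 higher and 13 lower. MSTRG.26139 fell there from 57.4 to 5.14 CPM at 2 months and from 10 UMIs to 0 at 6 months (log2 fold -3.60 ± 0.53, edgeR adjusted p = 1.29e-05). mikado.phaw_50.283870G1518 rose from 2.84 to 24.7 CPM at 2 months and from 3.96 to 10.8 CPM at 6 months (log2 fold 2.44 ± 0.56, edgeR adjusted p = 0.0195). Those levels rested on 4 and 24 UMIs at 2 months and on 4 and 7 UMIs at 6 months. Without the block, MSTRG.26139 had a log2 fold of -2.28 without regenerated replicate 1 and -7.59 without regenerated replicate 2, and mikado.phaw_50.283870G1518 had 1.31 without regenerated replicate 2. In cluster 9, with 7 calls, MSTRG.29922 rose (log2 fold 2.27 ± 0.38, edgeR adjusted p = 1.01e-05), from 56.7 to 365 CPM at 2 months and from 58.0 to 194 CPM at 6 months. With the 0-month uninjured library added and no block its log2 fold was 0.73 and did not pass (edgeR, adjusted p = 1). Leaving out 1 of the other libraries from that fit gave 0.35 without uninjured replicate 2, 0.31 without uninjured replicate 3, 1.10 without regenerated replicate 1 and 0.17 without regenerated replicate 2. In cluster 16, MSTRG.29580 fell (log2 fold -2.21 ± 0.39, edgeR adjusted p = 2.92e-05), from 1689 to 686 CPM at 2 months and from 3968 to 428 CPM at 6 months. Free RNA would give 15.5% and 40.9% of its UMIs there in the uninjured and 130% and 55.2% in the regenerated libraries, at 6 and 2 months, and its log2 fold was -1.37 without the block and without uninjured replicate 2.

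MSTRG.38102 was called lower in 4 clusters, more than any other gene. In cluster 9 it fell from 1227 to 386 CPM at 2 months and from 1449 to 550 CPM at 6 months (log2 fold -1.53 ± 0.28, edgeR adjusted p = 6.00e-05). Its level was lower in the regenerated library of both pools in all 18 clusters tested, and over all nuclei it fitted at a log2 fold of -1.02 ± 0.21, which did not pass (edgeR adjusted p = 0.764). Free RNA would give 41.3% to 67.8% of its UMIs in cluster 9. In the other clusters that called it, free RNA would give 82.6% to 87.7% (cluster 1), 69.4% to 95.4% (cluster 4) and 53.3% to 93.55% (cluster 7). With the expected free RNA subtracted, a step added after seeing the data, it was lower in both pools in 13 of the 18 clusters. Cluster 4, one of the 4 that called it, was not among them, with 32.5 CPM in uninjured and 44.2 CPM in regenerated legs at 6 months after the subtraction. It was chosen for the number of clusters that called it, after the values were seen.

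Of the 94 calls, 83 had the same direction in both pools, and 11 did not. The calls were chosen by a fit to the same 2 pools, so a shared direction was partly built in. A lower call of cluster 1, counted among the 83, had a log2 ratio of -0.04 at 2 months and -4.70 at 6 months. Among the 11, the single call of cluster 14, mikado.phaw_50.283355aG1206, had a log2 ratio of 3.01 at 2 months and -0.85 at 6 months. With adjustment over all clusters together, 74 of the 94 passed. In simulated counts the same test made more false calls than its threshold promises, 19% of calls in cluster 1, 13.8% in cluster 4 and 8.55% in cluster 14. Those rates depend on the simulated dispersions, which varied between genes with 6 degrees of freedom in every comparison. In the real counts edgeR estimated no gene-specific spread in 7 of the 9 clusters with a call, so the real rates may differ. The calls also depended on the pairing and the tool: without the pool as a block edgeR called 0 of them (1656 of 67476 tests at an unadjusted p under 0.05), and DESeq2 called 2, neither among the 94. A fit without the block counts differences between pools as spread. Over all nuclei the fitted coefficient of variation was 0.162 with the block and 0.308 without it. Fewer calls without the block are therefore no test of changes within pools. That unblocked fit of 4 libraries is also the fit without uninjured replicate 1, the 0-month library, so the latter adds nothing. With 1 library left out as well as the block, edgeR called 0 without uninjured replicate 1, 3 without uninjured replicate 2, 8 without uninjured replicate 3, 72 without regenerated replicate 1 and 6 without regenerated replicate 2.

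Gene by gene, the ratios at 2 months had no linear relation to those at 6 months. Over the 8308 genes with at least 50 UMIs in each of the 4 libraries, the log2 ratios of regenerated to uninjured legs in the 2 pools had Pearson r = -0.0033 across genes, and 49.7% had the same sign. At 2 months, 67 genes were over 2-fold higher and 31 over 2-fold lower in the regenerated library. At 6 months, 26 were higher and 88 lower. With the same sign in both pools, 5 genes passed 2-fold. How many would do so by chance was not computed. Each pool had 1 library per arm, so these ratios have no replicate check.

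**Figure D3:**
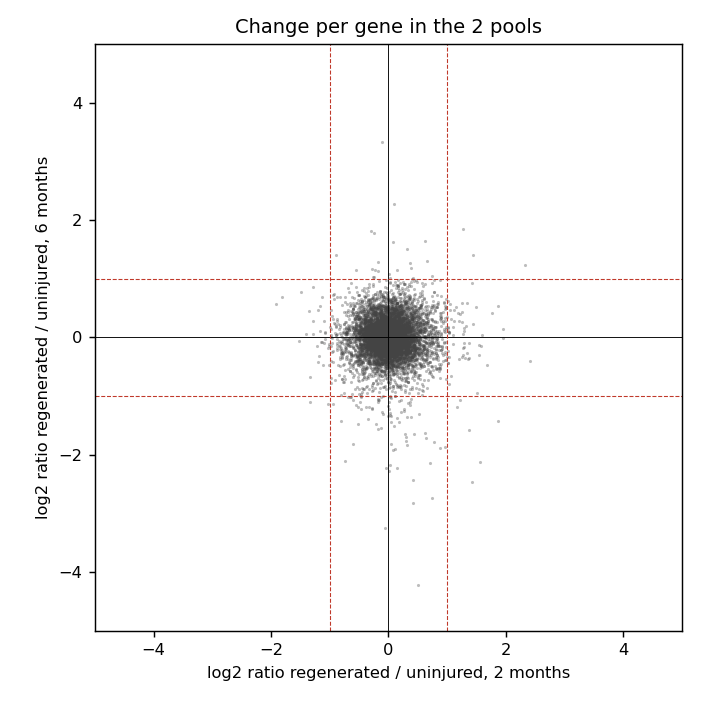
Log2 ratio of regenerated to uninjured legs per gene at 2 months (x axis) and at 6 months (y axis), centred on the median, for 8308 genes. Dashed lines mark 2-fold; the cloud has no slope (r = -0.0033), and 5 genes lie beyond 2-fold in both pools with the same sign.

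The mitochondrial share of UMIs followed the pool. Kept nuclei held 3.07% mitochondrial UMIs in the 0-month library, 3.23% and 3.08% in the uninjured and regenerated libraries at 6 months, and 5.81% and 6.87% at 2 months. The RNA of empty droplets would give 2.65%, 2.58%, 2.57%, 4.81% and 5.86% in the same order. None of the 15 mitochondrial genes tested passed (edgeR, lowest adjusted p = 0.995). Cox1, a subunit of cytochrome c oxidase, had a log2 fold of 0.04 ± 0.24. The small ribosomal RNA rrnS had a log2 ratio of -0.84 at 2 months and 0.21 at 6 months, and Nad6, a subunit of complex I, 0.80 and -0.38.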

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

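The tests of cluster 15 by doublets and by free RNA were set before their results were seen. The tests of a shifted cluster and the 3 tests of the genes low at 6 months were chosen after. Of the latter, the free RNA test replaced an earlier form, based on CPM in the clusters with the smallest excess, after that form's result had been seen.

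In the 2-month pool, cluster 3 took 1.16 times the share in regenerated legs that it took in uninjured legs, and at 6 months 0.847 times, with exact intervals that did not overlap in either pool. The mitochondrial share of UMIs was 1.18 times as high in regenerated legs at 2 months and 0.954 times at 6 months. Of the 94 calls within clusters, 11 had opposite directions in the 2 pools. None of these differences between pools was tested, since each pool had 1 library per arm.

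Barcodes off the lists of nuclei entered no fit, and the empty droplets among them served only to estimate free RNA. Mitochondrial genes made up 51.0% of the UMIs of the empty droplets of the 2-month regenerated library, against 29.1% to 41.6% in uninjured libraries. In its 527 barcodes off the list with over 100 UMIs the median was 48.1%, against at most 38.6%. At 6 months the difference went the other way, with 33.5% in regenerated against 35.9% in uninjured legs in empty droplets, and 27.8% against 32.1% in the other barcodes.

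Cluster 15, with 7.75% and 7.62% of the nuclei at 6 months and at most 10 nuclei in any other library, is a group of nuclei of 1 pool. Doublets would be mixtures, but 60% of its 125 describing genes lay above 2 times their highest level in any other cluster of those libraries. Free RNA would put these genes in empty droplets, where their share of UMIs was 8.55% of that in the cluster's nuclei at most. A cluster shifted as a whole in that pool would leave a gap elsewhere, and the largest shortfall of another cluster's share was 0.224 percentage points, in cluster 6. The nearest cluster by profile was cluster 1 (Pearson r = 0.884). Its share of the remaining nuclei ran from 22.33% to 30.35% in the libraries of the other pools. A gap in cluster 1 could be hidden in that range, so the test cannot decide for it. A difference between the animals, legs or dissections of the 6-month pool may account for cluster 15. Pool and time cannot be told apart here, and no test separates them.

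At 6 months, 88 genes were over 2-fold lower in regenerated legs and 26 over 2-fold higher. For 73 of the 88 the uninjured library of that pool was the highest of all 5, with a median log2 excess of 1.04 over the other pools, while the regenerated library lay at -0.35; for the 31 genes lower at 2 months the uninjured library was the highest for 13. Genes picked for a low ratio tend to have a high denominator, so part of this comes with the selection. Free RNA was not the source of most of it, since the excess UMIs of these genes per empty droplet were 3.40% of the excess per nucleus, and shifts in cluster shares gave 0.835% of the median log2 ratio, or 15.2% with clusters made without correction between libraries, 1 of which held 11.1% of the nuclei of that library and at most 0.376% of any other. Without the nuclei of that uncorrected cluster the median log2 ratio of the 88 genes, not centred, was -1.07, against -1.20 with all nuclei. A feature of that uninjured library may explain these genes as well as regeneration would, and with 1 library per arm this stays open.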

How the results depend on the processing

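Over all nuclei, edgeR called 0 genes with and without the pool as a block (808 and 209 at an unadjusted p under 0.05) and 0 in each fit that left out a library, against 2 with DESeq2, 8 without the filter (5 higher, 3 lower) and 2 with thinned counts. MSTRG.2350 passed under those 3 settings and MSTRG.28103 under the last 2. MSTRG.2350 was itself left out with the genes of over 10% free RNA, and MSTRG.28103 fell under the count filter without cluster 15. The 94 calls within clusters were less stable. Settings that changed the clusters also changed what was tested, against 18 clusters and 67476 tests in the main fit. At 500 UMIs or more 7 clusters were tested (27624 tests), at resolutions 0.25 and 1 15 and 22 clusters, and without mitochondrial genes 16. The number of calls was 0 without the pool as a block in 4 or in 5 libraries (1656 and 2313 at an unadjusted p under 0.05), 0 to 72 without the block and without a library (72 without regenerated replicate 1), 2 with DESeq2, 27 at 500 UMIs or more, 29 with thinned counts, 34 without genes of over 10% free RNA (19 higher and 15 lower, against 34 and 60), 57 with doublets kept, 57 and 58 at resolutions 0.25 and 1, 47 when clustered without mitochondrial genes, and 197 without the filter. Of the 94, 5 were among the 72 (40 higher, 32 lower), 30 remained among the 34, 13 among the 29, 66 among the 197, and 91 of the 109 with DESeq2 size factors. Unblocked fits count differences between pools as spread, so the calls they lose are no test of changes within pools. For the other settings the cause was not tested.

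For the 24 gene and cluster pairs named by rule, 54 of 103 values in blocked settings and 6 of 166 in unblocked ones stayed past the threshold. 1 reversed: mikado.phaw_50.000203bG1926 in cluster 9, at -0.84 without the block and without regenerated replicate 1 (-0.84 to 1.40 over the fits without a library). Cluster shares gave 0 calls in every setting run but 1, which left out uninjured replicate 2 and called cluster 15 (0 to 1 over the fits without a library): that comparison no longer has the pool's own control. The share of genes with the same sign in both pools was 48.0% at 200 UMIs or more, against 49.7%; the cause was not tested. The r and share distance of regenerated and contralateral legs moved by less than the SD of the 3 pairs of uninjured libraries in each of the 3 settings tried for each. Distances between pools moved by more: from 14.7% to 10.7% between the 0-month and 2-month uninjured libraries at resolution 0.25, and from 12.0% to 8.52% between the 0-month and 6-month ones without cluster 15, a setting chosen after seeing the data.

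A blocked fit without 1 library has no residual degrees of freedom, so libraries were left out only without the block, where a lone regenerated library is assumed to vary like the uninjured ones. Leaving out uninjured replicate 1 gives the same fit as the 4 libraries without the block, so the unblocked values hold that fit under both names. The gene list tests were not run, because the files do not pair gene identifiers with names. Depth limits single calls: 38 of the 94 had fewer than 10 UMIs in at least 1 library, 19 of them in cluster 1. Of the 24 pairs named by rule, 12 were left out with the genes of over 10% free RNA, a limit that also removes a gene with 0 UMIs in 1 library.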

Other observations

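All tests of explanations in this part were chosen after the values were seen.

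Several neighbouring gene models were higher in both regenerated libraries. On scaffold phaw_50.000203c, between 139435 and 708446, 5 of the 7 tested models, among them MSTRG.2350 and MSTRG.2351, had a median log2 ratio of 2.56 at 2 months and 1.39 at 6 months, and all 5 had their highest level in cluster 2. In that cluster MSTRG.2351 had 369 against 60.0 CPM at 2 months and 749 against 92.2 CPM at 6 months. In cluster 2 edgeR called 0 genes, with 197 at an unadjusted p under 0.05, and 23 without the filter on low counts. DESeq2 called 2 there, both among the 5 models, MSTRG.2351 (adjusted p = 6.32e-04) and mikado.phaw_50.000203cG42 (log2 fold 2.45, adjusted p = 0.0288). Over all nuclei edgeR called none of the 5, with 808 genes at an unadjusted p under 0.05. Within cluster 1 edgeR called MSTRG.2350 and mikado.phaw_50.000203cG42, with the limits given above. It also called the model at 519457 to 560009 in clusters 1 (edgeR adjusted p = 1.39e-09) and 11 (edgeR adjusted p = 4.62e-04). The cluster 11 call rested on 1 and 3 UMIs in the uninjured and 18 and 21 UMIs in the regenerated libraries, at 6 and 2 months. DESeq2 called 2 genes over all nuclei, MSTRG.2350 and the model at 519457 to 560009, both among the 5.

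Reads shared by overlapping models do not explain the group as a whole, since 60% of the 5 models, 3 of them, overlap no other of the 5. For the 2 that overlap, by 17647 bp, the ratio of their UMIs varied 2.20-fold between clusters, which leaves shared reads open. Shifts in cluster shares gave at most 22.1% of the median log2 ratio in either pool. Among the 20 genes with the smallest p higher in both pools, 5 had start positions within 500 kb, while none of 10000 random sets held more than 3, a share of 0.0001 with 1 added, the smallest they can give. That search was set up after the neighbours had been noticed, with a floor of 5 CPM, under the 10 CPM of the naming rule. Over 18 combinations of floor, set size and window the share was under 0.01 in 15 and reached 0.277 with the higher floor, 50 genes and a window of 250 kb, so chance placement was not excluded in every form. Random sets ignore that neighbouring genes can share expression, which was not tested. They also count each model as a separate gene. Of the 5 models, 4 lie on the minus strand, and whether any of them are parts of 1 gene was not tested.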
